A study of Mus musculus with 6 samples.

How the data were processed

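RNA from 6 cultures was measured on 6 one-colour Agilent mouse gene expression arrays (Cy3), 2 each for shControl, shTug1 clone 2 and shTug1 clone 3, with groups and replicates taken from the sample titles. The deposited scanner files hold an intensity for every spot: per the file headers, the processed signal is background-subtracted and spatially detrended, with a small substitute value where the signal was not above background. The files were made with Agilent Feature Extraction 11.0.1.1, per the submitters' processing notes and the file headers. A deposited value table for the series holds log2 values of 19819 probes. Set against the scanner values, each of its columns followed its own array (r from 0.9981 to 1, slopes from 0.928 to 1.05) and had nearly the same distribution as the others (medians 9.13, 9.125, 9.009, 8.985, 9.106 and 9.087), so it is on a log2 scale and not centred; how it was normalized and filtered is not given in the sources used here. Slide identity came from the file headers: 1 slide held both control arrays and the other slide the 4 arrays labelled shTug1.

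The array carries 43020 gene spots for 39429 probes. The files pair probes with transcript accessions but not with gene symbols, so symbols were taken by accession, without version, from a RefSeq table of mouse genes: 27234 probes matched (20659 symbols) and 12195 did not, and those stayed in the tests under their accession or probe name. Probe positions were not analysed here.

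Values were log2 of the processed signal minus the 75th percentile of each array over gene spots. Control spots and spots marked as non-uniform or as population outliers were left out, and spots of a probe were averaged. A probe was kept if it was well above background on both arrays of at least 1 group (25555 probes, of which 14 were lost to outlier marks). Each gene kept the probe with the highest mean signal, leaving 21470 genes, 15081 with a symbol and 6389 without; other probes that differed are named beside the gene. A probe well above background on no array of a side has only a bound there; where some arrays of a side measured it, their number is given beside its value. The fold is then given as at least the bright group's mean over the dim group's mean, each dim array being set to the higher of its own signal and the lowest signal well above background on that array.

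limma 3.58.1 in R 4.3.3 (with the package data.table, version 1.17.8) fitted 1 model with 3 group means (3 residual and 4.75 prior degrees of freedom). Contrasts were the mean of the clones minus control, each clone minus control, and clone 3 minus clone 2, two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. An exact split of 4 and 2 arrays cannot give a p below 0.0667, so no single-gene permutation test was used. camera tested 20 gene lists with a preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation; no list of the mean comparison passed then. Tests, groups, lists, the naming rule and most alternatives were set before the data were examined, with the exceptions named in the closing section. The log2 scale has no fixed zero across arrays, and list values are given relative to the median of all genes tested, which was −0.64 for the mean of the clones (−0.27 after quantile normalization).

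The genes named were Tug1, Ppargc1a, Tfam, Morc2a, Nphs1, Wt1 and Synpo; the 10 largest rises and 10 largest falls of the mean comparison among genes with a symbol, past the threshold, well above background on all 6 arrays and with all 4 arrays labelled shTug1 on the same side of both controls; up to 3 per direction that were dim on a whole side, ranked by bound; the 5 largest rises and falls of each other comparison; and up to 2 rises and 2 falls per list. Some genes that this rule chose are not reported here. The lists were neighbours of Tug1, PGC-1α axis and mitochondrial transcription, oxidative phosphorylation, mitochondrial dynamics and mitophagy, antioxidant genes, fatty acid oxidation, glycolysis, podocyte markers, actin cytoskeleton and adhesion, extracellular matrix and TGF-β targets, p53 targets, cell cycle, interferon response, inflammatory NF-κB targets, endoplasmic reticulum stress and ATF4 targets, polycomb genes, and markers of mesangial and stromal, endothelial, tubular and parietal, and immune cells. They were drawn from general knowledge and not from these samples.

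The model was tested on simulated data for the mean comparison over 21470 genes, in 20 simulations each. With 200 genes changed, 0% were recovered at a log2 change of 1, 0.1% at 2 and 96.2% at 4, with 9.25 false calls on average at 4. With 6000 genes changed by 2, 92% were recovered with 214 false calls, and with no change there were 0. camera called an oxidative phosphorylation list lowered by 0.5 in 20 of 20 simulations and 0 other lists. The simulated genes varied independently, with equal spread in all groups. The false calls therefore do not show how specific the tests are where genes vary together. The covariance, correlation and shared signs of the clones were set against 100 simulations of unchanged groups that shared the controls, again with equal spread in all groups.

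Alternatives were quantile normalization, normexp background correction with an offset of 50 (on the median spot signal, because no mean signal was among the columns used here), no filter on dim probes, a stricter filter (well above background on all 6 arrays), all probes, an intensity trend in the variance, only the groups compared, the replicate number as a block, the series value table, leaving out each array in turn, and, chosen after seeing the data, arrays centred on their medians and each array's score on the difference between the control arrays as a covariate. Slide could not be fitted as a block for comparisons with control, since each slide holds 1 side only; for clone 3 against clone 2 the 4 arrays of the shared slide were fitted alone.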

Results

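Gene expression was measured in conditionally immortalised mouse podocytes, the epithelial cells that wrap the glomerular capillaries, carrying a temperature-sensitive SV40 T antigen. The cells were grown at 33 °C, moved to 37 °C and differentiated for 10 days. They carried a lentiviral short hairpin RNA, either a scrambled control or a hairpin against the long noncoding RNA Tug1. The 6 arrays fall into 3 groups of 2: shControl, shTug1 clone 2 and shTug1 clone 3, with each group's pair described as biological replicates. The question addressed is which genes differ between podocytes with and without the Tug1 hairpin, in 2 independent clones. The 75th percentile of the deposited processed intensity was 324.3 and 363.3 on the control arrays, 1055 and 949.3 on the arrays labelled clone 2, and 569.2 and 831.6 on those labelled clone 3. The brightest 1% of gene spots began at 93050 and 65860 in control, 91510 and 82940 in clone 2, and 83530 and 96440 in clone 3. The bright end thus did not follow the 75th percentile. A bright probe with an equal signal on all arrays is therefore lower on the arrays labelled shTug1 after scaling to that percentile. Between 58.2% and 68% of the gene probes were well above background, and no spot was saturated. Across the genes tested, the 2 control arrays correlated at 0.9635, the clone 2 pair at 0.9819 and the clone 3 pair at 0.9901, and shControl replicate 2 correlated at 0.967 with shTug1 clone 3 replicate 1. On the first principal component (70.3% of the variance) the controls lay at −175.3 and −56.34, clone 2 at 103.4 and 95.66 and clone 3 at 5.517 and 27.01. Both control arrays were on 1 slide and all 4 arrays labelled shTug1 were on the other, so slide and hairpin cannot be told apart in any comparison with control. With 2 arrays per group, their number limits the precision.

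Tug1, a long noncoding RNA gene on chromosome 11, did not pass as lower on the arrays labelled shTug1, and was numerically higher than control on those labelled clone 2, which goes against that label. The only Tug1 probe well above background on all 6 arrays (A_52_P599162) gave a log2 signal, relative to each array's 75th percentile, of −2.68 ± 0.28 (SD, n = 2) in control, −1.86 ± 0.01 on the arrays labelled clone 2 and −3.17 ± 0.10 on those labelled clone 3. The single arrays read −2.88 and −2.49 in control, −1.86 and −1.87 in clone 2, and −3.10 and −3.24 in clone 3, where both lay below both controls. The log2 fold change of Tug1 for the mean of the clones against control was 0.16 (SE 0.29, limma adjusted p = 0.657). For clone 2 alone it was 0.82 (adjusted p = 0.0802), and for clone 3 alone −0.49 (adjusted p = 0.315). The median gene lay at −0.80 in clone 2 and −0.47 in clone 3, so in clone 3 Tug1 was close to the median gene. The difference in Tug1 between the clones, −1.31 (SE 0.34), did not pass the test either (adjusted p = 0.154). A second Tug1 probe (A_51_P119401) was well above background on 0 of 2 control arrays, 2 of 2 clone 2 arrays and 1 of 2 clone 3 arrays, at least 2.76-fold higher on the clone 2 arrays than in control. Its single arrays read −6.21 and −6.38 in control and −6.36 and −3.59 in clone 3, so its clone 3 mean was not below control. The remaining probe (A_55_P2123716) was not well above background on any array. Because of this, the groups are named below by their labels, and no direction is read as an effect of a lower Tug1.

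**Figure D1:**
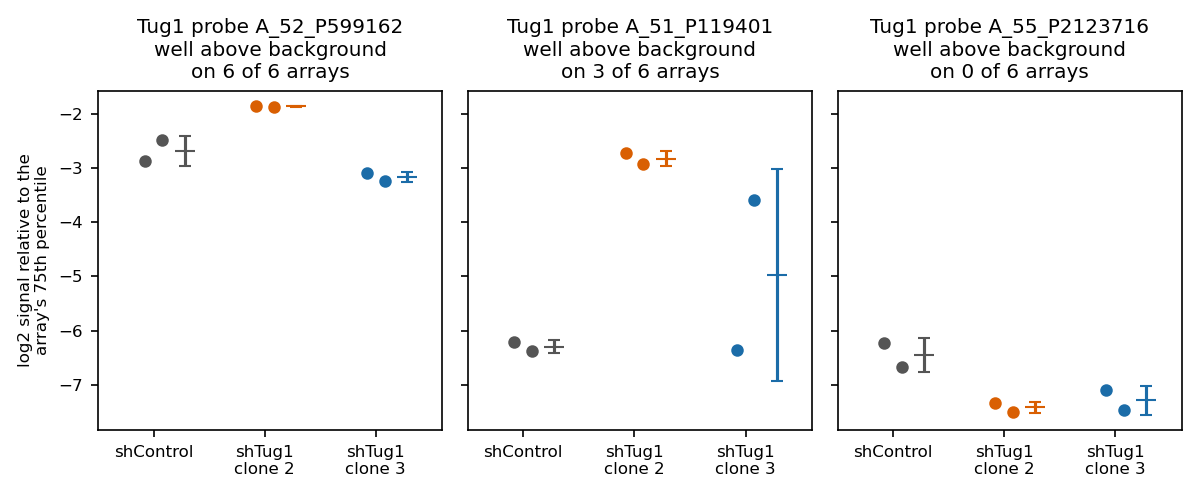
Log2 signal of the 3 Tug1 probes relative to the 75th percentile of each array. Points are single arrays and the bars beside them the group mean ± SD (n = 2). On the probe well above background on all arrays, the arrays labelled clone 2 (−1.86) lie above control (−2.68) and those labelled clone 3 (−3.17) below it.

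The largest rises on the arrays labelled shTug1 against control were those of Aldh2, the mitochondrial aldehyde dehydrogenase, with a log2 fold change of 4.85 (SE 0.56, adjusted p = 0.00568, 28.9-fold), and Dstn, the actin-depolymerising protein destrin, with 4.73 (SE 0.52, 26.6-fold). The focal adhesion gene Tns3 rose by 4.45, the translation initiation factor subunit Eif3b by 4.39, the calcium-binding calumenin gene Calu by 4.29 and the autophagy receptor gene Sqstm1 by 4.27. Of the 10 largest falls, Cnn1, the smooth muscle calponin, fell by 3.96 (SE 0.41, adjusted p = 0.00568, 15.5-fold), Fgf1, a fibroblast growth factor, by 3.58, Actg2, the enteric smooth muscle actin, by 3.57 and Gas6, a ligand of the TAM receptor kinases, by 3.12.

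The other rises named by the rule were Tmbim6 (4.06), which encodes an endoplasmic reticulum membrane protein that restrains cell death, Apmap (4.01), Dld (3.99), the dihydrolipoamide dehydrogenase shared by the mitochondrial 2-oxoacid dehydrogenases, and Cct8 (3.98), a subunit of the cytosolic chaperonin. The other falls were Nrip3 (−3.40), the leukotriene receptor gene Cysltr1 (−3.21), Itih4 (−3.04), Plppr3 (−3.03), the glutamate transporter gene Slc1a1 (−3.03) and Ms4a3 (−3.01). As the naming rule required, for all 20 genes the 4 arrays labelled shTug1 lay on the same side of both control arrays and adjusted p was under 0.05. It ranged from 0.00568 to 0.0194. Tmbim6 and Cct8 no longer passed without shTug1 clone 3 replicate 1, nor did Tns3, Sqstm1, Tmbim6 and Cct8 without shTug1 clone 3 replicate 2. In all, 0 of the 20 passed in limma with an array score as a covariate, described in the closing section. Without shControl replicate 1 the log2 fold changes of Tns3 (2.68), Sqstm1 (2.84), Tmbim6 (2.13) and Cct8 (1.94) were smaller by more than 1.5 times. Without shControl replicate 2 that of Cct8 (6.03) was larger by as much. The median gene itself had a log2 fold change of −0.64, so that relative to it Aldh2 was at 5.49 and Cnn1 at −3.32. Some genes were not well above background on either control array: Inka2 was at least 20.6-fold higher on the arrays labelled shTug1, the proton pump subunit gene Atp6v1h at least 19.3-fold and Ei24 at least 13.0-fold. Conversely, the ubiquitin ligase gene Rnf182 was at least 10.6-fold lower, Anpep, which encodes aminopeptidase N, at least 9.49-fold and the interleukin receptor gene Il17rb at least 6.40-fold, none of them well above background on the arrays labelled shTug1. Other probes of the same gene gave other values for Tns3 (0.18), Fgf1 (−0.87, on 1 of 2 clone 2 arrays), Cysltr1 (0.70, on 1 of 2 control arrays) and Inka2 (−0.84). The 2 probes of Dld gave 3.99 and 4.69, the latter on 1 of 2 control arrays.

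**Figure D2:**
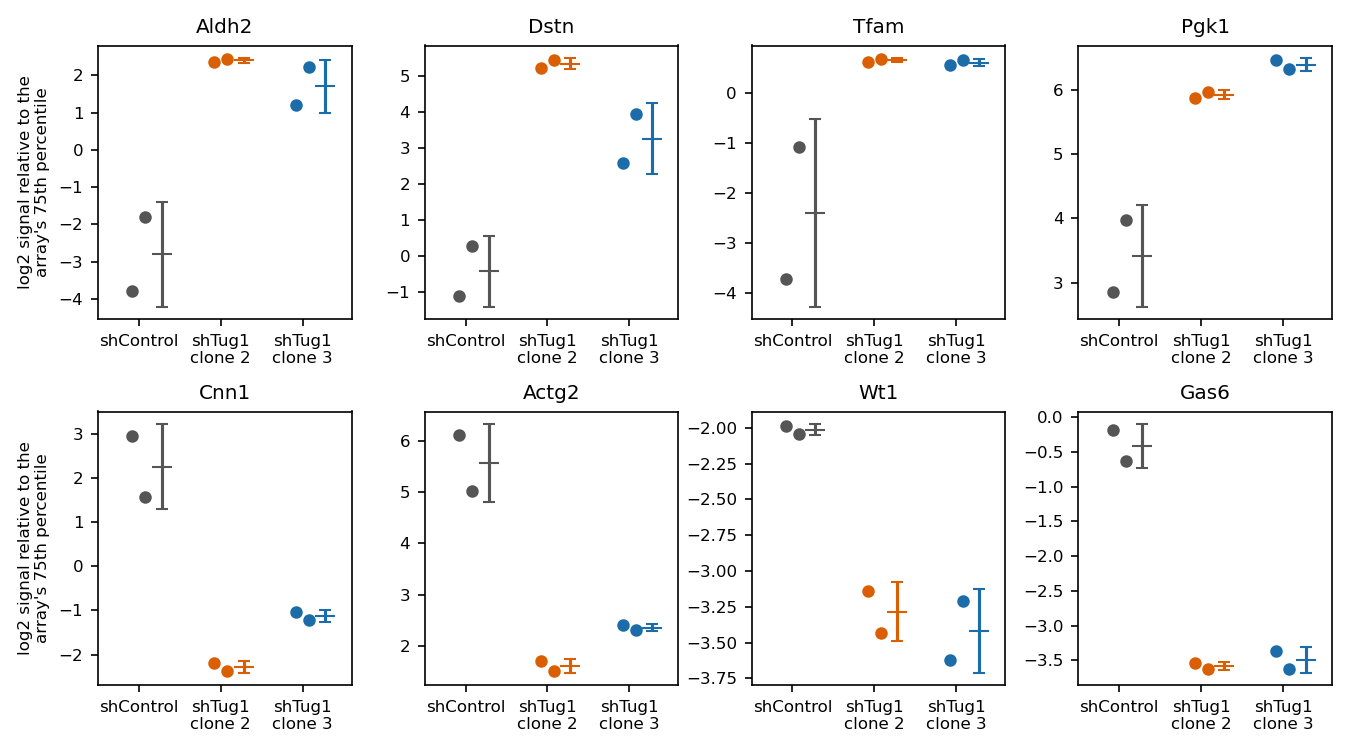
Log2 signal relative to the 75th percentile of each array for 4 genes that rose (top) and 4 that fell (bottom) on the arrays labelled shTug1. Points are single arrays and the bars beside them the group mean ± SD (n = 2), with a separate axis range for each gene. The control arrays of Aldh2, Dstn and Tfam lie far below the other 4 arrays and also apart from each other, and those of Wt1 lie above them and close together.

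Among the genes named in advance, Tfam, the mitochondrial transcription factor, rose by 3.04 (SE 0.65, adjusted p = 0.0163), and by 2.34 on a second probe measured on all 6 arrays. On the first probe the SD was 1.88 in control, 0.04 in clone 2 and 0.07 in clone 3, which the SE pools. The remaining tested probe of Tfam was not well above background on any control or clone 3 array. Wt1, the podocyte transcription factor, fell by 1.34 (SE 0.30, adjusted p = 0.0175), or −0.70 relative to the median gene. Synpo, which encodes the podocyte actin-binding protein synaptopodin, fell by 1.26 (SE 0.40, adjusted p = 0.0393) on its brighter probe, while a second probe rose by 2.41. The slit diaphragm gene Nphs1 had a log2 fold change of −1.15 (adjusted p = 0.0585) and the chromatin gene Morc2a of 0.47 (adjusted p = 0.324), and neither passed the test. Nphs1 did pass with the replicate number as a block (adjusted p = 0.0396), normexp correction (0.00451) and the stricter filter (0.0344). It stood at −1.83 without shControl replicate 2, −0.47 without shControl replicate 1 and −0.08 with the array score as a covariate. Morc2a stood at 0.01 and 0.94 without shControl replicate 1 or 2, 0.29 without shTug1 clone 3 replicate 1, and turned with the score (−0.22). Ppargc1a, the coactivator of mitochondrial biogenesis, was too dim to be tested: its brighter probe was well above background on 1 of 2 control arrays only and was at least 2.5-fold higher in control. The call of Synpo ended with quantile normalization (adjusted p = 0.0627, from 0.0527 to 0.514 over the settings that ended it) and without shControl replicate 1 (0.0859), shTug1 clone 2 replicate 1 (0.0596) or 2 (0.0636), or shTug1 clone 3 replicate 1 (0.0954) or 2 (0.121). Those of Tfam and Wt1 ended without shTug1 clone 3 replicate 1 (0.0517 and 0.0668) or 2 (0.0634 and 0.0676), and with the array score (0.117 and 0.12), although the log2 fold change of Wt1 stayed between −1.23 and −1.44 in these settings. The log2 fold change of Tfam was 1.71 without shControl replicate 1, 4.37 without shControl replicate 2, 1.96 with normexp correction and 0.97 with the score. That of Synpo was −0.62 without shControl replicate 1 and −0.26 with the score.

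The gene lists are given with how many of their measured members rose, fell or did not pass, counted on the log2 fold change itself, and with examples in parentheses relative to the median gene unless stated otherwise. Because the median gene lay at −0.64, counts of falls depend on the scaling. In the oxidative phosphorylation list, 5 of 77 subunits rose, 45 fell and 27 did not pass (5 and 52, adjusted over the list alone), but after quantile normalization 7 rose and 3 fell. The complex I genes Ndufa5 (−1.14) and Ndufs7 (−1.10) fell, while Ndufa10 (4.73), of the same complex and well above background on 1 of 2 control arrays, rose. The median of the list relative to all genes was −0.458 (camera adjusted p = 0.0387), a direction that turned with quantile normalization (0.0945) and with the deposited series values (0.137). Its call ended in both (adjusted p = 0.765 and 0.458) and with normexp correction (0.352), no filter on dim probes (0.0632) and the array score (0.0946), and its adjusted p was 0.874 with an estimated correlation. In the list of the PGC-1α axis and mitochondrial transcription, 4 of 20 rose, 9 fell and 7 did not pass (4 and 9, adjusted over the list alone; camera adjusted p = 0.771; 4 and 6 after quantile normalization). The mitochondrial helicase gene Twnk was at least 2.18-fold higher, and Mterf1a (−1.15) and the nuclear receptor gene Pparg (−0.92) fell. In the mitochondrial dynamics and mitophagy list, 4 of 18 rose, 5 fell and 9 did not pass (4 and 7, adjusted over the list alone; camera adjusted p = 0.712; 3 and 1 after quantile normalization). The list did pass, above the median gene, when all probes were counted (adjusted p = 0.0499, and adjusted p = 0.495 with an estimated correlation). The prohibitin gene Phb2 (3.14) rose. Oma1 passed upward but was not well above background on either control array, was on 3 of 4 of the others, and turned with normexp correction (log2 fold change −0.24). The fission genes Dnm1l (−1.02) and Fis1 (−0.65, with another probe at a log2 fold change of 0.90, on 1 of 2 control arrays) fell.

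Fatty acid oxidation genes went both ways: 6 of 25 rose, 6 fell and 13 did not pass (6 and 9, adjusted over the list alone; camera adjusted p = 0.292). The list did pass with normexp correction (adjusted p = 0.023, and adjusted p = 0.51 with an estimated correlation). After quantile normalization 5 rose and 1 fell. The acyl-CoA dehydrogenase gene Acads (3.27, well above background on 1 of 2 control arrays) and Ech1 (2.65) rose, and Cpt2 (log2 fold change −1.64) fell. Of 23 glycolysis genes, 4 rose, 9 fell and 10 did not pass (4 and 9, adjusted over the list alone; camera adjusted p = 0.771). After quantile normalization 6 rose and 2 fell. Phosphoglycerate kinase Pgk1 (3.38) and the pyruvate dehydrogenase kinase gene Pdk1 (3.32, on 1 of 2 control arrays) rose, and Pfkfb3 (−1.65) and Eno2 (−1.22) fell. Of 27 antioxidant genes, 5 rose, 9 fell and 13 did not pass (5 and 9, adjusted over the list alone; camera adjusted p = 0.373). After quantile normalization 7 rose and 1 fell. The antioxidant list did pass, above the median gene, with quantile normalization (adjusted p = 0.0467), normexp correction (0.023) and the series values (0.0399), but not with an estimated correlation in any of the 3 (adjusted p = 0.404, 0.695 and 0.523). The glutathione transferase gene Gsta4 was at least 4.84-fold higher, the glutathione synthesis gene Gclm (3.38) rose, and Gstm1 (−1.57, with another probe at a log2 fold change of 1.34) and Prdx2 (−0.80) fell. For the antioxidant, glycolysis and actin lists, the median relative to all genes was negative while the mean and the camera direction were positive.

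Of 27 podocyte markers, 1 rose, 10 fell and 16 did not pass (1 and 11, adjusted over the list alone; 0 and 4 after quantile normalization), and the list as a whole did not differ from other genes (camera adjusted p = 0.583). The laminin-binding integrin gene Itga3 (2.86) rose, and the scaffold gene Magi2 (−1.49, well above background on 2 of 4 arrays labelled shTug1) and the transcription factor gene Lmx1b (−1.01) fell. In the actin cytoskeleton and adhesion list, 8 of 32 rose, 13 fell and 11 did not pass (8 and 16, adjusted over the list alone; camera adjusted p = 0.712; 6 and 3 after quantile normalization). The list did pass, above the median gene, with the series values (adjusted p = 0.0399, and adjusted p = 0.481 with an estimated correlation). The integrins Itgb1 (3.06, with another probe at a log2 fold change of 0.99, on 1 of 2 control arrays) and Itga5 (2.88) were among the rises. Cnn1 and Actg2 led the falls. In the extracellular matrix and TGF-β list, 7 of 35 rose, 8 fell and 20 did not pass (7 and 8, adjusted over the list alone; 8 and 1 after quantile normalization). The crosslinking enzyme gene Lox (4.03, with another probe at a log2 fold change of 0.77) and the protease inhibitor gene Timp3 (3.88) rose, and the collagen gene Col5a2 (−0.77) and the membrane protease gene Mmp14 (−0.69) fell. This list lay 0.607 above the median gene (camera adjusted p = 0.0412, and adjusted p = 0.874 with an estimated correlation). That call ended with the stricter filter (adjusted p = 0.0597) and the array score (0.461).

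Of 32 cell cycle genes, 5 rose, 4 fell and 23 did not pass (5 and 0, adjusted over the list alone; 8 and 0 after quantile normalization, 6 and 9 after normexp correction). The list lay 0.434 above the median gene (camera adjusted p = 0.0412, and adjusted p = 0.874 with an estimated correlation). That call ended with the series values (adjusted p = 0.116) and the stricter filter (0.29). The centromeric histone gene Cenpa was at least 5.47-fold and the topoisomerase gene Top2a at least 2.63-fold higher, and the cyclin gene Ccne1 (−0.55) and Cdc20 (−0.47) fell. Of 22 p53 targets, 3 rose, 4 fell and 15 did not pass (3 and 4, adjusted over the list alone; camera adjusted p = 0.353; 5 and 1 after quantile normalization). The p53 list did pass, above the median gene, with quantile normalization (adjusted p = 0.0467) and normexp correction (0.023), but not with an estimated correlation (adjusted p = 0.404 and 0.51). Ei24 and Trp53 itself (3.27, on 1 of 2 control arrays) rose, and the death genes Bbc3 (−1.14) and Aen (−0.96) fell. Of 25 endoplasmic reticulum stress and ATF4 targets, 4 rose, 5 fell and 16 did not pass (4 and 5, adjusted over the list alone; camera adjusted p = 0.301; 2 and 0 after quantile normalization). The stress list did pass, above the median gene, with quantile normalization (adjusted p = 0.0181), normexp correction (0.023) and the series values (0.00585), but not with an estimated correlation in any of the 3 (adjusted p = 0.404, 0.51 and 0.481). Aldh18a1 (3.71), of proline synthesis, and the chaperone gene Dnajb9 (2.91, turning to a log2 fold change of −0.23 with the array score) rose, and Ddit4 (−0.77) and the asparagine synthetase gene Asns (−0.63) fell. Of 26 polycomb genes 0 rose in limma, 4 fell and 22 did not pass (0 and 3, adjusted over the list alone). After quantile normalization 1 rose and 3 fell. The falls included Aebp2 (log2 fold change −1.64, with another probe at −0.28) and Ezh1 (−0.85, with another probe at a log2 fold change of 0.96). The median of the polycomb list nevertheless lay 0.509 above the median gene (camera adjusted p = 0.401).

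Of 31 interferon response genes, 5 rose, 16 fell and 10 did not pass (6 and 16, adjusted over the list alone; camera adjusted p = 0.771; 2 and 11 after quantile normalization). Ifit2 (3.69, on 1 of 2 control arrays) rose, the peptide transporter gene Tap1 was at least 3.19-fold higher, and the ubiquitin-like modifier gene Isg15 (−1.50) and its protease Usp18 (−1.68) fell. Of 18 inflammatory NF-κB targets, 5 rose, 3 fell and 10 did not pass (5 and 3, adjusted over the list alone; camera adjusted p = 0.186; 5 and 2 after quantile normalization). The cyclooxygenase gene Ptgs2 (3.97, on 1 of 2 control arrays) and the chemokine gene Ccl7 (2.84) rose, and Lcn2 (−2.29) and the complement gene C3 (−1.78) fell. Among the 16 measured neighbours of Tug1, 1 rose, 8 fell and 7 did not pass (1 and 9, adjusted over the list alone; camera adjusted p = 0.771; 2 and 4 after quantile normalization), with Drg1 (2.10) rising and Pla2g3 (−1.34) and Inpp5j (−1.31) falling.

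Of 10 endothelial markers 0 rose and 6 fell (0 and 6, adjusted over the list alone; camera adjusted p = 0.292; 0 and 2 after quantile normalization), including Esam (−1.31) and Robo4 (−1.02, on 3 of 4 arrays labelled shTug1), and 4 did not pass. Of 10 immune cell markers 1 rose and 5 fell (1 and 6, adjusted over the list alone; camera adjusted p = 0.353; 0 and 5 after quantile normalization). Cd14 (1.74) rose, the macrophage receptor genes Csf1r (−2.30, with another probe at a log2 fold change of −0.32) and Itgam (−1.41) fell, and 4 did not pass. Of 10 mesangial, stromal and fibroblast markers 0 rose and 3 fell (0 and 2, adjusted over the list alone; camera adjusted p = 0.583; 0 and 2 after quantile normalization), including Cd248 (−0.97) and Meis1 (−0.69), and 7 did not pass. Of 13 tubular and parietal epithelial markers 1 rose and 4 fell (1 and 4, adjusted over the list alone; camera adjusted p = 0.771; 1 and 3 after quantile normalization). Cldn1 was at least 1.32-fold higher, although it turned with normexp correction (log2 fold change −0.22). Cdh16 (−1.60) and the water channel gene Aqp1 (−1.13) fell, and 8 did not pass.

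**Figure D3:**
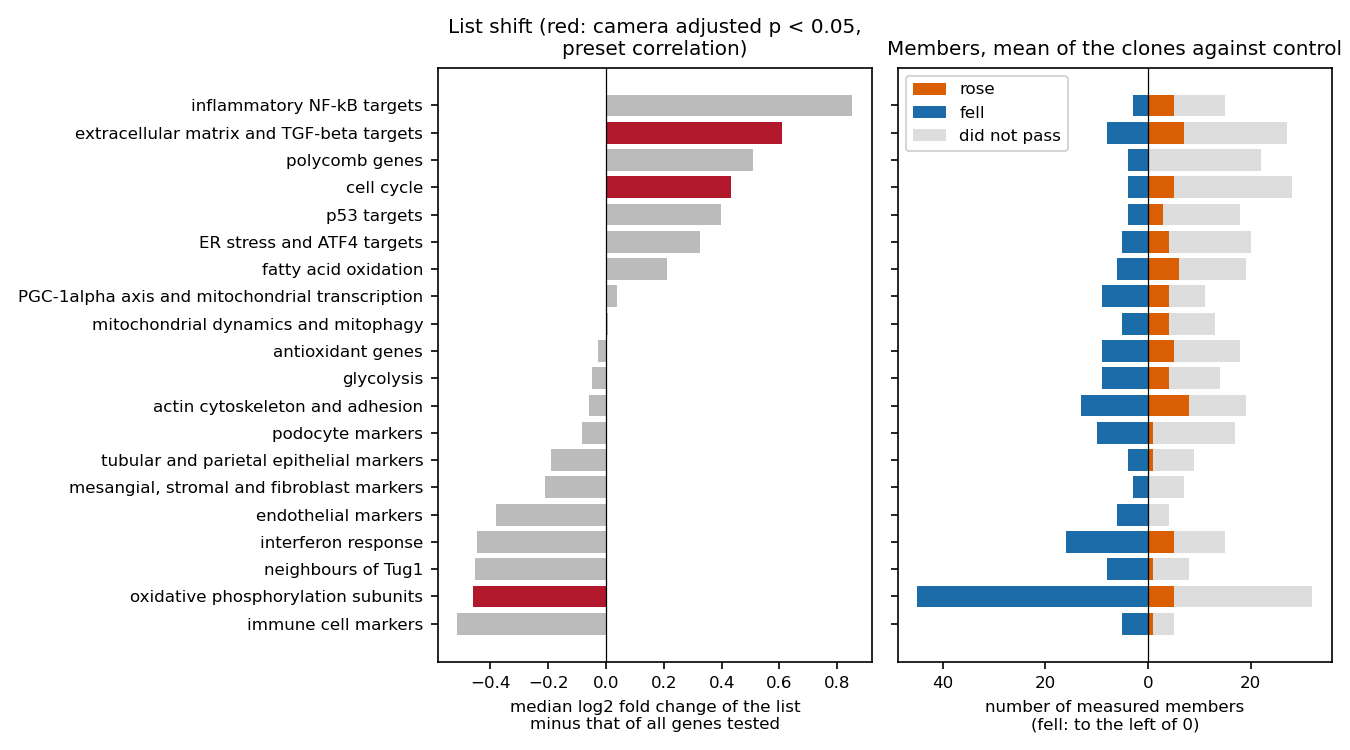
Left, median log2 fold change of each gene list for the mean of the clones against control, minus that of all genes tested, with red bars for lists past the camera threshold with a preset correlation. Right, numbers of members that rose, fell or did not pass. The oxidative phosphorylation list (−0.458) turned direction with quantile normalization (0.0945), and no list passed with an estimated correlation.

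In the limma fit, 8740 of 21470 genes differed between the mean of the clones and control at adjusted p under 0.05, 2183 higher and 6557 lower (25% higher), and 11375 at an unadjusted p under 0.05. That fit shared 1 spread per gene among the groups. It is the spread between the 2 arrays of a group, so the p-values do not cover variation from clone to clone. Differences between the cell lines that do not come from the hairpin cannot be told apart from it in comparisons with control. The SD of the replicate difference, however, was 1.06 in control, 0.54 in clone 2 and 0.52 in clone 3. These values cover the 7214 tested probes of genes with at least 2 such probes. The SEs of comparisons with control may therefore be too small, and these counts too high. Changes of 8-fold or more numbered 348 higher and 45 lower. Of the 348, 79 were not well above background on either control array, so that only a bound on their fold can be given. After quantile normalization 5846 genes differed, 2434 higher and 3412 lower (41.6% higher), and after normexp background correction 14726, 1967 higher and 12759 lower (13.4% higher), so the balance of rises and falls is not settled. With 1 array left out, its group keeps a single array, which the fit assumes to vary like the others. Counts from such fits, given below and as ranges in the closing section, depend on that assumption. The median gene lay at −0.39 without shControl replicate 1 and −0.92 without shControl replicate 2. It lay at −0.67 and −0.61 without shTug1 clone 3 replicate 1 or 2. The extracellular matrix call ended without shControl replicate 1 (adjusted p = 0.112), shTug1 clone 2 replicate 2 (0.0642) or shTug1 clone 3 replicate 1 (0.0511), and the cell cycle call without shControl replicate 2 (0.104), shTug1 clone 2 replicate 2 (0.0994) or either clone 3 array (0.0511 and 0.0609). The oxidative phosphorylation call ended without shTug1 clone 2 replicate 2 (adjusted p = 0.0642).

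Different probes of one gene often gave different changes. Gapdh, a glycolytic enzyme gene, had 7 probes designed from the same transcript, with log2 fold changes from −1.34 to 2.82. Across 3316 genes with at least 2 tested probes, the SD between probes of a gene was 1.20 on the log2 scale, and the intraclass correlation of the change was 0.134. Among probes well above background on all 6 arrays (2236 genes) these were 0.996 and 0.162. Of the 2204 such genes with a call on any probe, 361 were called the same way on all probes (98 higher, 263 lower), and 257 (11.7%) had probes called in opposite directions. The value of any gene measured by a single probe carries this limit.

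**Figure D4:**
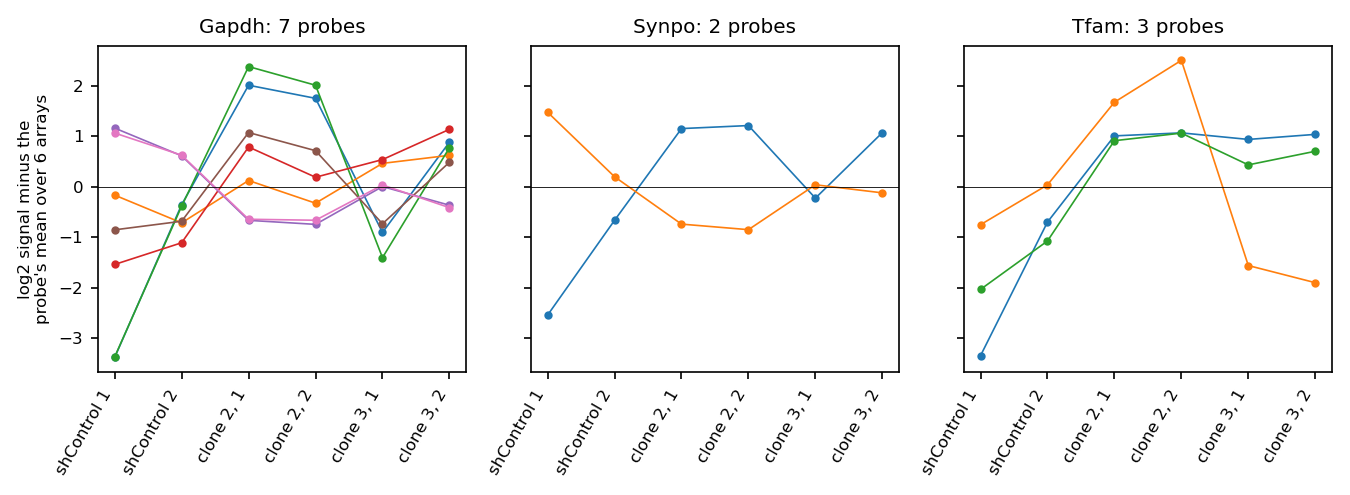
Log2 signal of each tested probe of Gapdh, Synpo and Tfam minus that probe's mean over the 6 arrays. Each line is a probe and each point an array, with the lines serving only to join the points of a probe. The 7 Gapdh probes range from −1.34 to 2.82 in log2 fold change against control, and the 2 Synpo probes move in opposite directions (−1.26 and 2.41).

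Each clone was then compared with control on its own. On the arrays labelled clone 2 the largest rises were Dstn (log2 fold change 5.77, SE 0.60), the proton pump accessory gene Atp6ap1 (5.50, SE 0.69), Calu (5.33), Aldh2 (5.20) and Eif3b (4.88), and the largest falls Cnn1 (−4.53, SE 0.48), Fgf1 (−4.27), Actg2 (−3.95), Nrip3 (−3.70) and Itih4 (−3.45). On the arrays labelled clone 3 they were Aldh2 (4.51, SE 0.65), Tns3 (4.36), Apmap (4.11), Eif3b (3.91) and Ivl (3.89), the cornified envelope gene involucrin, against Cysltr1 (−3.45, SE 0.39), Cnn1 (−3.38), Actg2 (−3.20), Nrip3 (−3.10) and Gas6 (−3.08). In clone 2, 9425 genes differed (2205 higher and 7220 lower, 23.4% higher), around a median gene at −0.80. In clone 3, 2004 differed (943 higher and 1061 lower, 47.1% higher), around a median gene at −0.47, and 7756 at an unadjusted p. After quantile normalization the counts were 5762 (2226 higher, 3536 lower, 38.6% higher) and 1745 (978 higher, 767 lower, 56% higher), and after normexp correction 15194 (13.3% higher) and 7033 (1434 higher, 5599 lower, 20.4% higher). Without shControl replicate 2 the median gene lay at −1.08 in clone 2 and −0.74 in clone 3. Without shTug1 clone 3 replicate 1 or 2 the median gene of clone 3 lay at −0.52 and −0.41. The clone 2 count fell to 3876 and 4850 without its own first or second array, and to 5063 without either clone 3 array.

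The genes called in both clones included Aldh2, Dstn, Tns3, Eif3b and Apmap among the rises and Cnn1, Actg2, Nrip3, Cysltr1 and Gas6 among the falls. In all, 1674 genes were called the same way in both clones, 832 higher and 842 lower, and 3 in opposite directions. Independent lists of these sizes would share 96.85 higher and 356.8 lower genes. Across genes, which are not independent replicates, the log2 fold changes of the clones had a covariance of 1.145 against 0.1063 in 100 simulations of unchanged groups against the same 2 controls, a difference of 1.039, and a correlation of 0.7894 against 0.5005. They had the same sign for 85.5% of genes, against 66.7% in the simulations. The simulations gave all groups an equal spread. However, the SD of the replicate difference, over 7214 probes, was 1.06 in control, 0.54 in clone 2 and 0.52 in clone 3. The simulated values may therefore be too low for controls that vary this much. The excess over them cannot decide how much change the clones share. The 2 controls cannot be split into pairs, so part of the overlap may come from the shared controls. The covariance was 0.6497 without shControl replicate 1 and 2.116 without shControl replicate 2. It was 1.238 and 1.052 without shTug1 clone 3 replicate 1 or 2. The range of the number of shared genes when 1 array is left out is given in the closing section.

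**Figure D5:**
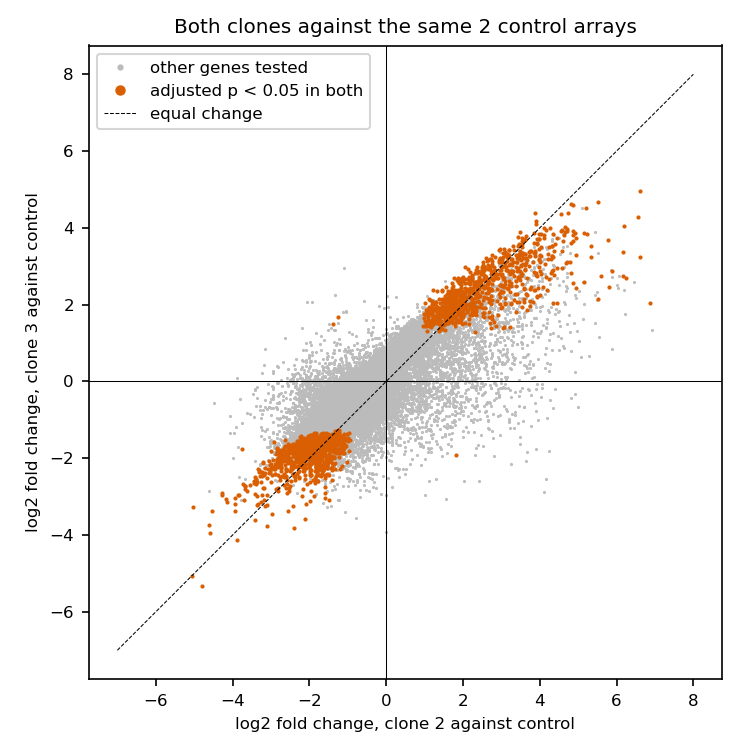
Log2 fold change against the same 2 control arrays of every gene tested, on the arrays labelled clone 2 (horizontal) and clone 3 (vertical). Orange points are the genes past adjusted p 0.05 in both, 1674 with the same sign and 3 with opposite signs, and the dashed line marks equal change.

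Clone 3 was compared directly with clone 2, within the slide that held both. The collecting duct water channel gene Aqp2 (log2 fold change 2.55, SE 0.39, adjusted p = 0.0292) and the epithelial shape gene Shroom3 (2.54, SE 0.44, adjusted p = 0.0432) were higher on the arrays labelled clone 3, as were Card14 (2.42), the collagen receptor gene Lair1 (2.36) and the short-chain fatty acid receptor gene Ffar3 (2.26). Lower on the arrays labelled clone 3 were the Golgi gene Golph3 (−4.96, SE 0.68, adjusted p = 0.0242), the lysosomal ceramidase gene Asah1 (−4.75, SE 0.56, adjusted p = 0.018), the hypoxia factor gene Hif1a (−4.62), the thioesterase gene Lypla1 (−4.43) and the RNA helicase gene Dhx15 (−4.39). In all, 278 genes differed, 74 higher and 204 lower in clone 3 (26.6% higher), around a median gene at 0.37, with 2518 at an unadjusted p. The count was 63 after quantile normalization (20 higher, 43 lower, 31.7% higher), 400 after normexp correction (42 higher, 358 lower, 10.5% higher), 565 with the 4 arrays of this slide alone, and 0 with the deposited series values (2460 at an unadjusted p). It was 0 without shTug1 clone 3 replicate 1 (1144 at an unadjusted p), 2 without shTug1 clone 3 replicate 2, 565 without either control array and 885 without shTug1 clone 2 replicate 2.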

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

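The results below stood out because the clones' effects against the same control differed in a direct test of clone 3 against clone 2, which was planned. In all, 278 of 21470 genes differed (74 higher and 204 lower on the arrays labelled clone 3). The named genes higher on the arrays labelled clone 3 had log2 differences of 2.55 for Aqp2, 2.54 for Shroom3, 2.42 for Card14, 2.36 for Lair1 and 2.26 for Ffar3. All 5 were lower than control on the arrays labelled clone 2 (from −2.01 for Lair1 to −2.94 for Shroom3) while on those labelled clone 3 they did not pass the test against control (from −0.40 for Shroom3 to 0.35 for Lair1, adjusted p from 0.497 to 0.847). The named genes lower on the arrays labelled clone 3 had log2 differences of −4.96 for Golph3, −4.75 for Asah1, −4.62 for Hif1a, −4.43 for Lypla1 and −4.39 for Dhx15. These 5 were higher than control on the arrays labelled clone 2 (from 3.23 for Lypla1 to 5.54 for Dhx15), while clone 3 lay between −1.20 for Lypla1 and 1.15 for Dhx15 and none passed the test. Hif1a and Dhx15 were well above background on 1 of 2 control arrays. With only 2 arrays in each group, no array could be tested as standing apart from its group. Without shTug1 clone 3 replicate 1 or 2, none of the 10 genes passed (adjusted p from 0.137 to 0.4 and from 0.054 to 0.253). Without shTug1 clone 2 replicate 1, Aqp2 (0.0596), Card14 (0.0737), Lair1 (0.0863) and Ffar3 (0.0591) did not pass, nor did Ffar3 without replicate 2 (0.0766). After quantile normalization Lair1 and Lypla1 passed and the other 8 did not, with adjusted p from 0.0513 to 0.202. None passed with the score (0.0825 to 0.159) or, of the 8 in it, with the series values (0.122 to 0.155), and 3 of 10 passed without a filter on dim probes. The log2 differences kept their direction: with the score from 1.86 to 2.17 and from −3.39 to −4.37. With the series values they ran from 2.19 to 2.46 and from −4.45 to −5.17. Shroom3 and Ffar3 did not pass with an intensity trend (0.0532 and 0.0558) or the stricter filter (0.0517 and 0.0557), nor Hif1a and Dhx15 with arrays centred on their medians (0.0797 each).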

How the results depend on the processing

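The score covariate, the centring on medians and the comparison of probes of one gene among bright probes alone were chosen after seeing the data; the other alternatives were planned. The log2 fold change of Tug1 for the mean of the clones, 0.16, stayed short of the threshold in every setting run, between −0.26 with normexp and 0.36 without shControl replicate 2; it was also negative with the score (−0.13) and without shControl replicate 1 (−0.03). Tug1 in each clone was not repeated under them. Counts for the mean of the clones, clone 2, clone 3 and clone 3 against clone 2 (8740, 9425, 2004 and 278) stayed within 1.5 times of these values except as follows, and the cause was not tested unless the setting itself shows it. Quantile normalization gave 5762 for clone 2 and 63 between the clones, with 5 lists past the threshold instead of 3, oxidative phosphorylation not among them. Normexp gave 14726, 15194 and 7033 for the comparisons with control, 6089 genes the same way in both clones, a covariance of 0.5733 and 6 lists. Without a filter there were 751 for clone 3, 91 between the clones and 673 shared; with the stricter filter, which tests fewer genes, 3078, 35 between the clones and 1 list, oxidative phosphorylation. Counting all probes gave 488 between the clones, an intensity trend 141. Fitting only the groups compared gave 5677 for the mean, where all 6 arrays were kept and both clones were taken as 1 group. With 4 arrays it gave 5063 for clone 2 and, between the clones, 565, the same 4 arrays as within their slide (565). The deposited series values gave 5379, 5446 and, between the clones, 0 in limma (2460 at an unadjusted p under 0.05). With the score as a covariate, which leaves 2 residual degrees of freedom, limma called 0 for the mean, 0 for clone 2 and 0 between the clones (5942, 4547 and 3059 at an unadjusted p under 0.05), 781 for clone 3, 0 shared, a covariance of 0.6195 and 1 list, cell cycle. camera with an estimated correlation called 0 lists without any other change. Leaving out 1 array in turn, counts ranged from 404 to 14268 for the mean, 3876 to 14938 for clone 2, 0 to 11414 for clone 3, 0 to 885 between the clones and 0 to 10479 shared, the covariance from 0.6497 to 2.116 and the lists from 0 to 3; a group left with 1 array was assumed to vary like the others.

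The replicate block gave 8783, 9443, 2523 and 442, and changed the count over 1.5 times only between the clones. The replicate numbers are not shown to pair the arrays: the correlations of replicate differences were −0.038 between control and clone 2, 0.106 between control and clone 3 and −0.0886 between the clones.

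The oxidative phosphorylation list turned from −0.458 to 0.0945 with quantile normalization and 0.137 with the series values. Of the named genes with a call, Oma1 (−0.24) and Cldn1 (−0.22) turned with normexp, and Dnajb9 (−0.23) with the score; the cause was not tested. Of 110 values that the naming rule chose in the mean comparison, 24 lost their call with quantile normalization, 5 with normexp (4 gained one and 2 turned), 10 without a filter, 21 with only the groups compared, 16 of 86 with the series values, 26 without shControl replicate 1, 49 and 71 without shTug1 clone 3 replicate 1 or 2, and 103 with the score. By more than 1.5 times, 47 moved without shControl replicate 1, 14 without shControl replicate 2, 68 with the score, 25 with normexp, 18 with quantile normalization and 18 of 86 with the series values. Signal over background limits the dim genes: 58.2% to 68% of probes were well above it.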

Other observations

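The genes of the first paragraph were chosen after their values were seen, as were the list tests between the clones and the tests of a shared gradient and of the slide (a like correlation, 0.51 across all genes, had been seen), of exchanged labels, of the score for the large rises, of a Tug1 dose and of the other probes of the large changes (values of some of these probes had been seen); the allowance of 1 SE for Tug1's percentile and the coverage limit for other probes were also added after the values were seen. Within the matrix list, the basement membrane collagens Col4a1 (2.19 relative to the median gene, adjusted p = 0.0231) and Col4a2 (2.11, adjusted p = 0.0189) rose on the arrays labelled shTug1, and also with quantile normalization, normexp correction and the series values (adjusted p from 0.00254 to 0.0276). The fibrillar collagen Col5a2 (−0.77) fell in the same 4 settings and Col1a2 (−0.51) in all but quantile normalization (adjusted p = 0.0527), while Col1a1 (0.08) did not pass in any of them and Col3a1 (0.31) passed only with normexp, at a log2 fold change of −0.71 (adjusted p = 0.0273). In the fatty acid list, Cpt1a (2.39), the outer mitochondrial carnitine transferase, and the dehydrogenase gene Hadh (2.32) rose in each of these settings. Acadl (2.55) did not pass with quantile normalization (adjusted p = 0.06), nor the carnitine carrier gene Slc25a20 (1.83) with normexp (adjusted p = 0.34). The falls of Acadvl (−0.52) and Acaa2 (−0.59) did not pass with quantile normalization (adjusted p = 0.317 and 0.202) or with the series values (0.346 and 0.185).

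Between the clones, 4 lists passed camera with a preset correlation. Relative to the median gene, polycomb genes (−0.48, adjusted p = 0.0149), podocyte markers (−0.51, adjusted p = 0.0302) and inflammatory NF-κB targets (−0.51, adjusted p = 0.0302) were lower on the arrays labelled clone 3 than on those labelled clone 2, and oxidative phosphorylation subunits higher (0.26, adjusted p = 0.00198). With an estimated correlation none passed (adjusted p = 0.383 for each of the lower lists and 0.978 for oxidative phosphorylation), and no single member of these lists differed between the clones at adjusted p under 0.05. These comparisons between the clones were not among the list tests that were planned, and were not repeated under the other settings.

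Probes of the same gene moved apart between the groups. The scaling of the arrays is argued against by the SD between probes, which was 0.968 times as large after quantile normalization. The slide as the whole cause is argued against by a relation within slides: probes lower than the gene's other probes on control array 1 than on control array 2 were also lower on clone 3 than on clone 2 arrays (r = 0.405, rho 0.445 over 7214 probes, which are not independent; at most 0.0463 in size when shuffled; 0.507 among probes well above background on all arrays). A gradient shared by all arrays, such as RNA integrity or the reach of the labelling would give, could produce that value of 0.405. It stays open as a hypothesis. The array scores were 0 and 0.999 in control, 1.51 and 1.5 in clone 2, and 1.02 and 1.09 in clone 3. Those of the controls are 0 and about 1 by construction. The other scores are measured from control array 1, so noise on that array enters all of them, and they do not test the gradient. A change in transcript isoforms was not tested.

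On the probe well above background on all 6 arrays, Tug1 did not pass as lower on the arrays labelled shTug1, being numerically higher than control in clone 2 and lower in clone 3. The clone 3 change of −0.49 was close to the median gene (−0.47). A second probe was above both controls (−6.21 and −6.38) on 1 clone 3 array (−3.59) and between them on the other (−6.36). On both clone 2 arrays (−2.73 and −2.93) that probe was above both controls. That the gradient hides a lower Tug1 is argued against for clone 2, whose Tug1 change stood at the 65.2 percentile of 500 genes matched on mean signal and control difference (55.4 with the change lowered by 1 SE). For clone 3 it stays open, because the percentile of 28.6, past the bound of 25 set beforehand, falls to 17 with the change lowered by 1 SE. Exchanged labels of control and clone 2 would need a lower Tug1 on the clone 3 than on the clone 2 arrays, and that difference of −1.31 missed the threshold, so that they cannot be told apart from the labels as given. Hairpins that left these Tug1 transcripts in place would be a biological explanation, which was not tested.

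Changes of 8-fold or more comprised 348 rises and 45 falls. Among the rises, 79 were not well above background on either control array, and the values below include them. The bootstrap intervals given for them resampled genes, with the arrays held fixed. They leave out the uncertainty that comes from the small number of control arrays. A value past a bound is therefore not shown to hold for other arrays. For the rises, the score as a covariate left 54.4% of the median log2 fold change (95% bootstrap interval 49.9 to 58.1; 3.47 with a median SE of 0.588 before, 1.89 with 0.4 after, 0 called), past neither bound (50 and 75), so that the gradient as their whole cause cannot be told apart from other causes. Of the rises, 344 were lower on control array 1 than on array 2 and 340 lower on clone 3 than on clone 2 arrays, relative to the median gene (19 and 15 of the 45 falls), an order in line with the gradient that the choice of genes on the same arrays also favours. A Tug1 dose would need a lower Tug1 in clone 2, where it was 1.31 higher without passing the threshold, and stays open with the labels. The second Tug1 probe was also higher in clone 2 than in clone 3, by 2.15 (SE 0.79). It was well above background on only 1 of 2 clone 3 arrays, and the remaining probe on no array. For the falls, the score as a covariate left 86% (95% bootstrap interval 79.6 to 90.2; −3.26 with a median SE of 0.392 before, −2.80 with 0.497 after), past the bound of 75, and 0 of 45 remained called in limma with fewer residual degrees of freedom. This cannot decide against the gradient as their whole cause. Within groups the score differed mainly between the control arrays (0 and 0.999), a difference set by its construction. Genes chosen by the threshold tend to be those whose control arrays were alike, and these keep most of their change. Other probes of these genes do not decide whether expression changed, since only 42 of the 348 rising and 3 of the 45 falling genes had one, short of the 80% required: their median relative log2 fold change was 0.757 (95% bootstrap interval 0.414 to 1.73) for the rises and 0.0296 (−0.292 to 1.28) for the falls, the latter past its bound against a change in expression. A real fall or rise in the shTug1 cultures stays open, as does the slide, which cannot be told apart from the hairpin.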
